A study of Mus musculus with 6 samples.

How the data were processed

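The series measured poly-A RNA by sequencing in macrophages from mouse skin wounds, taken at day 3 post injury from mice of the genotypes control and Gls_cko, with 3 libraries each. Per the labels' protocols, each library pooled 6 wounds from 3 mice, and the cells were drawn from digested wound skin with magnetic beads against F4/80, a surface protein of mature mouse macrophages. The Cre line behind the conditional knockout is not given in the sources used here.

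Values are raw read counts per gene, deposited as whole numbers and made with featureCounts 1.6.0 over coordinate-sorted alignments, per the file headers. The annotation was Ensembl release 106 on GRCm39, per the file headers, and every coordinate given here is on that build. The command line in the headers carried no option for strand, read pairs, multiple mapping or quality, so strand was not used. Reads shared by overlapping genes or by near-identical copies could not be assigned to a single gene and may be missing from the counts. Genes with near-identical copies, among them Hba-a1, Hbb-bs, Lyz1, Lyz2 and Stfa2, are therefore uncertain as single genes. Trimmomatic, featureCounts and DESeq2 are named in the submitters' processing notes, and the aligner is not given in the sources used here. The same command line listed 3 further alignment files that have no column in the table and were not analysed here. Exon length in bases was taken from the same table, per the file headers.

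Symbols came from the gene name table of the mouse reference for 52081 of the 55414 gene IDs (94%), with older names matched through a RefSeq table of GRCm38.p6 used for names only. The GC content of each gene's longest transcript came from a GRCm38 annotation and was known for 99.6% of the tested genes.

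Groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries scaled with TMM factors, and the quasi-likelihood F test applied to a model with the group as its only term. Benjamini-Hochberg adjustment ran over all tested genes, with a threshold of 0.05. CPM are counts scaled by the TMM-adjusted library total, given as mean ± SD over 3 libraries. Total counts ranged from 38109243 to 163704965 per library, so that a floor of 3 counts corresponded to 0.0233 to 0.121 CPM. Where a group held 0 counts, a bound on the fold change was taken against a floor of 3 counts over the group. At 1 to 3 counts, the ratio is given with an exact conditional 95% interval. Shares of single libraries carry exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since reads from amplified libraries are not independent molecules.

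Before the data were examined, 44 gene lists, the rule for named genes and most alternatives were fixed. Lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over 43 lists. Each list was also run with the correlation estimated from the data, and with fry, which tests whether a list's genes move on balance in a single direction without comparing them with other genes. The rule named the tested glutamine genes, the 8 largest rises and 8 largest falls among genes that passed with groups that did not overlap and a mean of at least 5 CPM, and up to 4 members of each list with the smallest p.

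Alternatives fixed beforehand were RLE and upper-quartile factors, library size only, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, a minimum absolute log2 fold change of 1, the replicate number as a block, mitochondrial, ribosomal RNA and haemoglobin genes left out, and each library left out in turn. Alternatives chosen after seeing the data were thinning to the smallest total, voom with library weights, cameraPR on the edgeR statistics, and removal of each library's trend with GC content and exon length as an offset, fitted by loess with a span of 0.3.

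The scripts were tested on simulated counts for 16563 genes with the means and library totals of the real libraries. The edgeR test recovered 10 of 100 genes changed 8-fold and 56 of 100 changed 64-fold, with 0 false calls among 66. In 20 simulated sets with no change and each group's own spread, edgeR called 0 genes, whereas camera called a median of 17 lists (range 10 to 23) and cameraPR a median of 7 (highest 11). With a trend over GC content and length added, false calls numbered 36 without its removal and 3 with it. The added trend was fitted in the same way as the one removed, so this checks the script only. Trend removal also takes out real changes that go with GC content or length. The fit included genes at 0 counts in the Gls_cko libraries, so that it may move well-detected genes too far.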

Results

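RNA-seq read counts were collected for 6 libraries of macrophages isolated from mouse skin wounds at day 3 post injury. The 3 control libraries held 56293077, 80147261 and 63195690 counts. The 3 Gls_cko libraries, from mice with a conditional knockout of the glutaminase gene Gls, held 163704965, 38109243 and 66532043 counts. The question behind the comparison of these genotypes is how glutamine use by wound macrophages bears on neutrophil recruitment, gene regulation and repair. Read counts of the fraction measure RNA only, and neither glutamine use, recruitment of neutrophils nor repair.

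The wound macrophage fractions of the genotypes differed in cell type markers as well as in metabolic genes. Counts per fraction cannot tell whether changes in metabolic and inflammatory genes, Gls included, came from macrophages, the mix of cells or library quality. At equal totals, a Gls_cko library held at most 12478 genes with at least 10 counts, and a control at least 15926. Of the 3240 genes that fell, 2275 had no counts in any Gls_cko library. Fold bounds for such genes cover counting only, and do not bound the level in the cells. Neutrophil genes such as S100a9 and Cxcr2, inflammatory cytokine genes such as Il1b, and the cystine transporter gene Slc7a11 were higher in all 3 Gls_cko libraries than in any control library. Macrophage genes such as Lyz2, C1qc and Csf1r, and endothelial and fibroblast genes such as Plvap and Col3a1, were lower in all 3. Of 16563 genes tested, 4452 (26.9%) passed the edgeR quasi-likelihood test after adjustment, 1212 of them higher and 3240 lower in Gls_cko. With library size as the only scaling, 674 were higher and 3851 lower. The groups' ranges did not overlap for 9545 genes (57.6%), where chance gives 10%.

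The Gls_cko libraries held fewer genes than the controls, before and after thinning. Genes with at least 10 counts numbered 17268, 19065 and 17418 in the control libraries and 13228, 7809 and 13082 in the Gls_cko libraries. After thinning every library to the smallest total, these numbers were 16033, 16734 and 15926 against 11870, 7809 and 12478. The 10 most abundant genes took 11.4%, 9.71% and 11.5% of counts in the controls and 16.4%, 21.6% and 14.1% in Gls_cko. Exact 95% intervals of these shares were 11.425% to 11.442%, 9.7008% to 9.7137% and 11.468% to 11.484% in the controls, and 16.404% to 16.415%, 21.553% to 21.579% and 14.069% to 14.086% in Gls_cko. The most abundant gene was Apoe, a lipid carrier of macrophages, in each control library, Cd14, a receptor for bacterial lipopolysaccharide, in Gls_cko replicates 1 and 3, and Actb in Gls_cko replicate 2, genes named after their values were seen. The biological coefficient of variation was 0.345 among controls and 1.57 among Gls_cko libraries. Of the 3240 genes that fell, 2275 had 0 counts in all Gls_cko libraries, and 14 of those that rose had 0 counts in all controls.

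**Figure D1:**
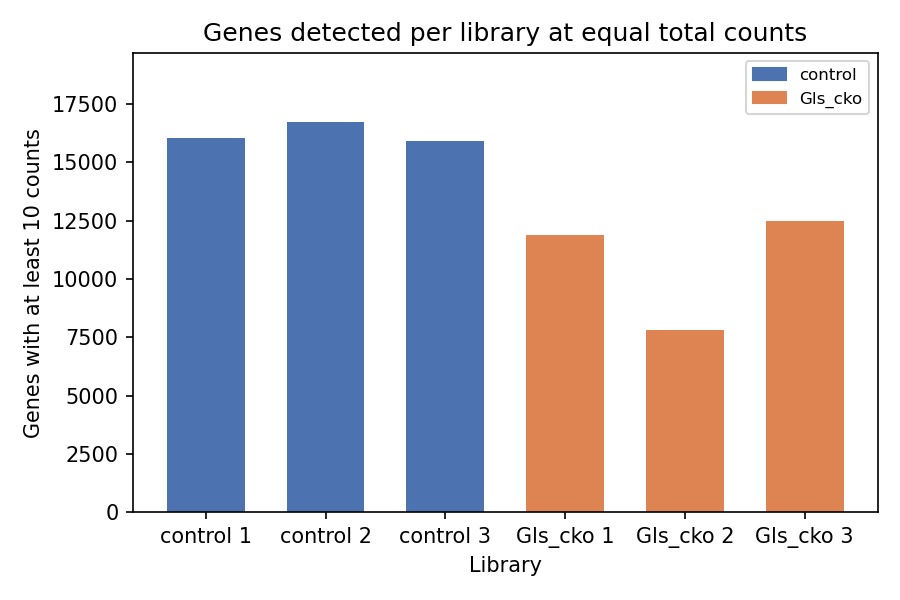
Number of genes with at least 10 counts in each library after thinning every library to the smallest total, as a bar per library. The Gls_cko libraries held 7809 to 12478 genes and the control libraries 15926 to 16734.

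Gls (ENSMUSG00000026103, chromosome 1, 52202607 to 52272391), which encodes the glutaminase that turns glutamine into glutamate, fell by 2.17 on the log2 scale (SE 0.59; edgeR adjusted p = 0.0399). Its level was 75.2, 62.6 and 85.9 CPM in the control libraries and 28.9, 6.79 and 14.1 CPM in the Gls_cko libraries, a mean of 74.6 ± 11.6 against 16.6 ± 11.3 (SD, n = 3). Every Gls_cko library lay below every control library. A count per gene cannot show whether a deleted exon is missing. The call passed in 10 of 19 alternatives, with edgeR, DESeq2 or limma adjusted p from 0.0049 to 0.173. It was lost without control replicate 1 (adjusted p = 0.117), 2 (0.0994) or 3 (0.130), and without Gls_cko replicate 3 (0.106), and the log2 fold change was −2.87 without Gls_cko replicate 1.

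Among 29 tested genes of glutamine metabolism, 1 rose and 4 fell, and 1 rose and 3 fell when adjusted over the list alone. Slc7a11, the cystine-glutamate exchanger (ENSMUSG00000027737, chromosome 3, 49846975 to 50398063), rose from 87.8 ± 21.6 to 2328 ± 774 CPM (log2 fold change 4.73, SE 0.39, edgeR adjusted p = 0.00335). Slc1a5, a glutamine importer, fell from 135 ± 35.4 to 13.6 ± 4.74 CPM (log2 fold change −3.32), but stood at 0.45 after removal of the trend with GC content and length. Pycr1, of proline synthesis, and Ctps, of CTP synthesis, had 0 counts in all Gls_cko libraries and were at least 74.2-fold and 979-fold lower. Neither passed without control replicate 1 (adjusted p = 0.0547 and 0.0545), and the bounds were 29.1 and 383 without Gls_cko replicate 1, and 524 for Ctps without control replicate 2. Glul, the glutamine synthetase, did not pass (log2 fold change −0.95, edgeR adjusted p = 0.0644), and nor did Gls2, the liver-type glutaminase (−1.62, 0.525), Asns, the asparagine synthetase (1.87, 0.379), or Cad, of pyrimidine synthesis (−4.33, 0.244). Each passed in 1 or more alternatives. Gls2 (edgeR adjusted p = 0.0193) and Cad (0.0139) passed without Gls_cko replicate 3, the only Gls_cko library with counts of either. Their fitted log2 fold changes there, −7.40 and −11.8, stand against 0 counts and give a direction only. Asns (2.47, edgeR adjusted p = 0.033) and Glul (−1.20, 0.00893) passed without Gls_cko replicate 2. With voom weights, Cad, Asns and Glul passed (0.0419, 0.0231 and 0.0262), and Glul passed with limma-voom (0.0234) and library size only (0.0103) as well. After trend removal, Glul stood at 1.03 and Gls2 at 0.46. The list did not stand apart from other genes in camera (adjusted p = 0.705; 0.733 with an estimated correlation). Its median log2 fold change was −0.41, and 0.77 after removal of the trend.

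Genes of central carbon metabolism moved in both directions. Acod1, which makes itaconate from a TCA cycle intermediate, rose from 12.01 ± 0.485 to 2649 ± 475 CPM (log2 fold change 7.78, SE 0.30, edgeR adjusted p = 0.000636). Ogdh, of the alpha-ketoglutarate dehydrogenase complex, and Acly, the ATP citrate lyase, fell (−2.15 and −2.06), but stood at 0.96 and 0.89 after trend removal. Of the 24 tested TCA cycle genes, 1 rose and 3 fell, the same numbers as adjusted over the list alone. Camera gave an adjusted p of 0.705 (0.852 with an estimated correlation), upwards, although the median was −0.39 and the mean −0.56. Slc2a3, a glucose transporter, rose by a log2 fold change of 6.83, and Pfkp and Pgk1, glycolytic enzymes, by 2.17 and 1.46, whereas Pfkm, the muscle-type phosphofructokinase, was at least 361-fold lower. Pgk1 did not pass with library size only (0.69), nor Pfkm without control replicate 1, 2 or 3, and its bound was 141 without Gls_cko replicate 1. Of 23 tested glycolysis genes, 3 rose and 1 fell, as when adjusted over the list alone, with camera upwards at adjusted p = 0.0841 (0.708 with an estimated correlation). The list did pass camera with upper-quartile factors (0.032), without control replicate 1 (0.045) and without Gls_cko replicate 2 (0.015). Their median was 0.02, but −0.13 with RLE factors and −0.70 with library size only, and their mean was −0.28. After trend removal 13 glycolysis genes rose and 1 fell. Of 36 tested genes of oxidative phosphorylation, 5 rose and 0 fell in the edgeR test, with 10 higher and 0 lower at an unadjusted p under 0.05, and 0 changed when adjusted over the list alone. The list stood above other genes in camera (adjusted p = 0.000262; 0.227 with an estimated correlation), with a median of 0.15 that was −0.62 with library size only. Camera also called this list upwards in 19 of 20 simulated sets without change. Ndufa6 of complex I and Cox7b of complex IV rose (1.5 and 1.57) but did not pass with library size only, without a filter (Cox7b alone, 0.0549), without control replicate 1, 2 or 3, or after trend removal, where Ndufa6 stood at 3.30 (edgeR adjusted p = 0.0556) and Cox7b at −0.20 (0.747).

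Stress and chromatin genes changed in small numbers. Ddit3, a transcription factor of the integrated stress response, rose (log2 fold change 3.01) and Ddit4, an inhibitor of mTORC1, fell (−3.29). After trend removal Ddit4 stood at −0.75 and did not pass, nor did it with voom weights (adjusted p = 0.108). Of the 25 tested ATF4 targets, 4 rose and 3 fell, as when adjusted over the list alone, with camera upwards at adjusted p = 0.247 (0.721 with an estimated correlation). Their median was −0.06, but 0.23 with upper-quartile factors. Among 21 histone and DNA demethylases that use alpha-ketoglutarate, 4 rose and 1 fell, and 3 rose and 1 fell when adjusted over the list alone. Kdm7a and Kdm3a, demethylases of histone H3 lysine 9, rose (1.81 and 1.44), the latter not with library size only (0.66) or without control replicate 1, 2 or 3. Tet1, a DNA demethylase, had 89 counts over the controls and 1 over Gls_cko, a ratio of 71.8 (95% interval 12.6 to 2870), which was 44 without control replicate 2 and at least 9.37 without Gls_cko replicate 1. Camera placed the demethylases upwards at adjusted p = 0.089 (0.443 with an estimated correlation), which passed without Gls_cko replicate 3 (0.0367). Their median was −0.15, but 0.16 with upper-quartile factors. Of 35 tested histone methyltransferases, acetyltransferases and deacetylases, 0 rose and 2 fell in the edgeR test, with 4 higher and 3 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Ehmt2, a histone H3 lysine 9 methyltransferase, and Hdac5, a deacetylase, fell (−2.59 and −2.53), but stood at 1.62 and 0.81 after trend removal, and did not pass without control replicate 1 or 3. Hdac5 also did not pass without control replicate 2 or Gls_cko replicate 3 (adjusted p = 0.142 and 0.12), with upper-quartile factors (0.0662), the stricter filter (0.0666) or robust dispersion (0.0519), and stood at −3.69 without Gls_cko replicate 1. This list had camera adjusted p = 0.747, upwards (0.765 with an estimated correlation), and a median of −0.73 that was 1.17 after trend removal.

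Neutrophil markers were the group with the largest rise among the lists of immune cells. S100a9 and S100a8, which form the calprotectin complex of neutrophils, rose from 3.70 ± 0.959 to 12610 ± 3644 CPM and from 9.10 ± 3.04 to 12360 ± 5548 CPM (log2 fold changes 11.74 and 10.41). Cxcr2, a chemokine receptor of neutrophils, rose from 1.42 ± 0.231 to 1288 ± 152 CPM (9.82, SE 0.34, edgeR adjusted p = 0.000636). Il1r2, a decoy receptor for interleukin 1, and Sell, the L-selectin of circulating leukocytes, rose by log2 fold changes of 8.80 and 7.37. Of 29 tested neutrophil markers, 23 rose and 1 fell, and 25 rose and 1 fell when adjusted over the list alone. Camera placed the list above other genes (adjusted p = 1.4e-20; 0.161 with an estimated correlation), as it did in 18 of 20 simulated sets without change. Their median log2 fold change was 7.36, and 7.53 after trend removal.

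Monocyte markers had a median log2 fold change of 1.78. Of 17 tested, 9 rose and 3 fell, as when adjusted over the list alone, with camera adjusted p = 6e-06 (0.161 with an estimated correlation). Plac8, Ifitm6 and Hp, all high in inflammatory monocytes and granulocytes, rose by log2 fold changes of 4.07, 6.00 and 5.29.

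**Figure D2:**
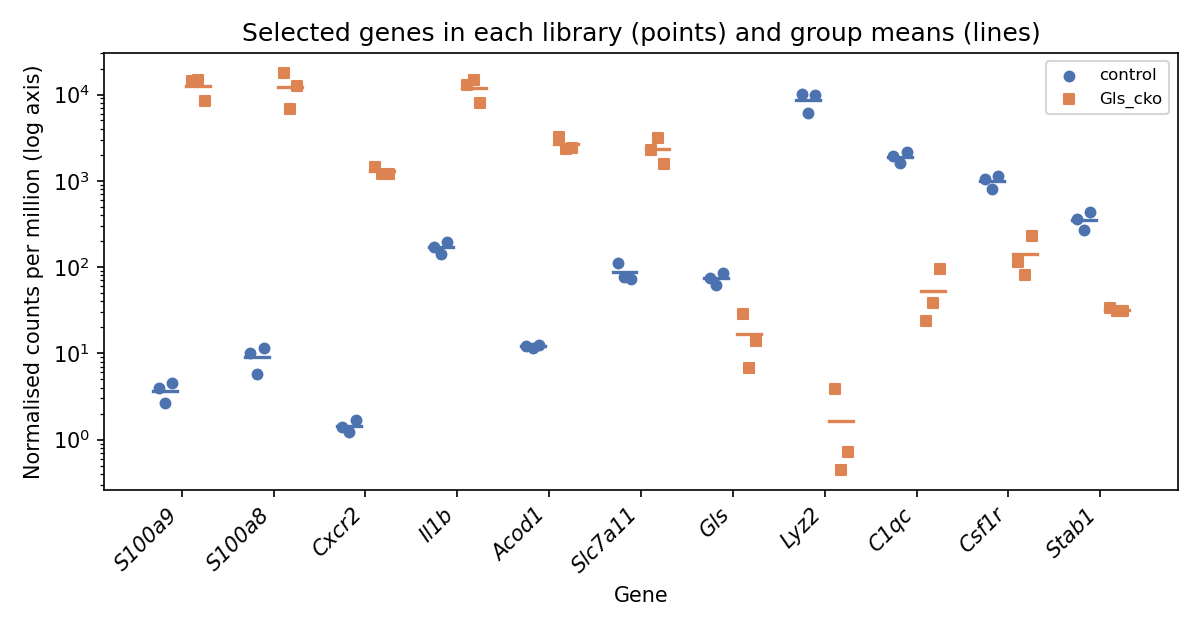
Level of 11 genes in each library, in normalised CPM on a log axis, with a line at each group's mean. The Gls_cko points of S100a9, S100a8, Cxcr2, Il1b, Acod1 and Slc7a11 lie above all control points, and those of Gls, Lyz2, C1qc, Csf1r and Stab1 below.

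Some genes for neutrophil-attracting chemokines and cytokines rose. Il1b, encoding interleukin 1 beta, rose from 169 ± 27.6 to 11950 ± 3501 CPM (log2 fold change 6.15, SE 0.39, edgeR adjusted p = 0.00187), and Il1f9, encoding interleukin 36 gamma, by a log2 fold change of 8.34. Of 21 tested, 11 rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone, with camera adjusted p = 1.2e-08 (0.161 with an estimated correlation). S100a8 and S100a9 are members of this list as well as neutrophil markers. Chemokines for monocytes and lymphocytes went both ways. Ccl5 and Ccl17, which draw T cells, rose (4.63 and 7.0), whereas Ccl8, which draws monocytes, fell from 1083 ± 428 to 49.5 ± 30.1 CPM and Cxcl14 was at least 464-fold lower. Neither Ccl17 (without control replicate 3, adjusted p = 0.0535) nor Cxcl14 (without control replicate 1 or 3, 0.0671 and 0.0587) passed in every fit. Ccl17 stood at 7.64 without control replicate 2 and 6.38 without Gls_cko replicate 1, where the bound of Cxcl14 was 181, and Ccl8 went from −4.45 to −5.04 without Gls_cko replicate 2. Of 17 tested, 3 rose and 6 fell, and 4 rose and 7 fell when adjusted over the list alone, with camera downwards at adjusted p = 0.787 (0.852 with an estimated correlation).

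Pro-inflammatory genes and NF-kB targets rose in part. Fpr2, a receptor for formyl peptides, and Il23a, a subunit of interleukin 23, rose by log2 fold changes of 5.96 and 7.68. Of 29 tested pro-inflammatory genes, 11 rose and 1 fell, and 16 rose and 2 fell when adjusted over the list alone, with camera adjusted p = 7.7e-09 (0.161 with an estimated correlation). Traf1, Sod2 and Birc3, which limit cell death or oxidative damage downstream of NF-kB, rose (2.74, 1.78 and 2.02). Of the 25 tested NF-kB targets, 12 rose and 2 fell, and 12 rose and 3 fell when adjusted over the list alone, with camera adjusted p = 8.8e-08 (0.227 with an estimated correlation). Among 41 tested genes of the interferon response, 10 rose and 1 fell, as when adjusted over the list alone. Rtp4, Isg20 and Ifi44, all induced by interferon, rose (2.91, 4.72 and 3.74), whereas Iigp1, an interferon-induced GTPase, had 17831 counts over the controls and 2 over Gls_cko, a ratio of 7190 (95% interval 1990 to 59400). This ratio was 2670 without control replicate 2 and at least 1880 without Gls_cko replicate 1, and Il23a stood at 8.34 without control replicate 3. The interferon list had camera adjusted p = 0.00021, upwards (0.478 with an estimated correlation), and a median of 0.10 that was −0.05 with RLE factors and −0.59 with library size only.

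Antigen presentation genes gave few calls. Cd80 and Cd86, costimulatory molecules, rose (3.46 and 1.17), Cd86 not with library size only (0.42) or without control replicate 1, 2 or 3. Of 14 tested genes of MHC class II presentation, 2 rose and 0 fell in the edgeR test (5 and 0 at an unadjusted p under 0.05), as when adjusted over the list alone, with camera upwards at adjusted p = 0.000128 (0.496 with an estimated correlation). H2-Eb1, a class II chain, stood at 1.69 and did not pass (edgeR adjusted p = 0.0654), but did with upper-quartile factors (0.0307), limma-voom (0.0494), voom weights (0.00483), trend removal (0.0101) and without Gls_cko replicate 2 (0.00408). Among 16 tested genes of MHC class I presentation, 1 rose and 2 fell, and 0 rose and 2 fell when adjusted over the list alone. B2m, the class I light chain, rose (1.29), and Tap2 and Tapbp, of peptide loading, fell (−1.84 and −0.996), but after trend removal they stood at −0.86, 2.10 and 2.95. Without control replicate 1 or 3, none of these class I genes passed (adjusted p from 0.0555 to 0.13). B2m also did not pass without control replicate 2 (0.144), without Gls_cko replicate 1 (0.12) or 3 (0.0958), with library size only (0.373), the stricter filter (0.0591) or DESeq2 (0.0806), nor Tapbp with upper-quartile factors (0.0577). Camera placed the class I list upwards at adjusted p = 0.747 (0.912 with an estimated correlation), although its median was −0.21, or 0.09 with upper-quartile factors.

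Macrophage identity markers were lower as a group. Lyz2, encoding the lysozyme of macrophages and neutrophils (chromosome 10, 117113236 to 117118226), fell from 8655 ± 2203 to 1.67 ± 1.88 CPM (log2 fold change −12.31, SE 1.26, edgeR adjusted p = 0.00608), and stood at −13.9 without Gls_cko replicate 1. Lyz1, its near-identical copy, rose from 54.3 to 332 CPM (log2 fold change 2.61, edgeR adjusted p = 0.0154). Csf1r, the receptor that macrophages need for survival, fell from 991 ± 176 to 141 ± 76.6 CPM (−2.81), but stood at 0.07 after trend removal. Fcer1g, a chain of Fc receptors, rose (2.06), which did not pass after trend removal (1.20). Of 23 tested markers, 2 rose and 12 fell, and 3 rose and 15 fell when adjusted over the list alone. The number that fell was 5 without control replicate 1, 8 without control replicate 2, 6 without control replicate 3, 8 without Gls_cko replicate 1, and 6 after trend removal. Camera placed the list below other genes (adjusted p = 0.0204; 0.514 with an estimated correlation), which did not pass without Gls_cko replicate 1, 2 or 3 (0.308, 0.0588 and 0.169). The median was −2.12, and −0.42 after trend removal.

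Many markers of skin-resident macrophages fell as well. Of 16 tested, 0 rose and 10 fell in the edgeR test (0 and 11 at an unadjusted p under 0.05), and 11 fell when adjusted over the list alone, with camera downwards at adjusted p = 0.000863 (0.496 with an estimated correlation). Without Gls_cko replicate 1 the list did not pass (0.0603), and 5, 6 and 5 members fell without control replicate 1, 2 or 3. Selenop, a selenium carrier protein of resident macrophages, fell from 2557 ± 433 to 273 ± 190 CPM (log2 fold change −3.23), Wwp1 by 3.51 on the same scale, and Cd209f, a C-type lectin, was at least 4792-fold lower (1880-fold without Gls_cko replicate 1). Selenop stood at −3.91 without Gls_cko replicate 3. The median was −2.65, and −2.27 after trend removal, where 7 fell.

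Genes linked to repair and to the clearance of dead cells went both ways. Stab1, a scavenger receptor, and C1qc, of complement C1q, fell (log2 fold changes −3.47 and −5.19), but did not pass after trend removal (−0.22 and −2.72), and C1qc stood at −5.98 without Gls_cko replicate 3. Il1rn, the interleukin 1 receptor antagonist, Spp1, encoding osteopontin, and Cd209a, a C-type lectin, rose (2.88, 2.57 and 4.61). Of 35 tested repair-associated genes, 5 rose and 9 fell, and 6 rose and 11 fell when adjusted over the list alone. The number that fell was 3, 5 and 3 without control replicate 1, 2 or 3, and 15 without Gls_cko replicate 2. Camera placed them downwards at adjusted p = 0.963 (0.977 with an estimated correlation), with a median of −0.84 that was 0.11 after trend removal. Of 27 tested genes of efferocytosis and phagocytosis, 3 rose and 7 fell, as when adjusted over the list alone, with camera downwards at adjusted p = 0.111 (0.496 with an estimated correlation). Their median was −1.89, and 4 members fell without control replicate 1. This list passed camera without control replicate 2 (0.03). Anxa1, a mediator of resolution, its receptor family member Fpr1, and Ptgs2, the inducible cyclooxygenase, rose (2.30, 5.69 and 2.88). In the list of resolution and lipid mediators, 6 of 21 tested rose and 3 fell, and 6 rose and 5 fell when adjusted over the list alone, with camera upwards at adjusted p = 0.00193 (0.227 with an estimated correlation).

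Lysosomal genes gave more falls than rises, but not after trend removal. Lamp1, a lysosomal membrane protein, and Grn, encoding progranulin, fell from 1342 ± 179 to 117 ± 24.4 CPM and from 1573 ± 427 to 149 ± 33.4 CPM (log2 fold changes −3.52 and −3.40). Hexa, a hexosaminidase, and Npc1, a cholesterol exporter, fell (−2.70 and −2.61). None of these passed after trend removal, where they stood at −1.76, 0.20, −0.51 and −1.41. Of 29 tested lysosome and TFEB genes, 2 rose and 9 fell, and 2 rose and 13 fell when adjusted over the list alone. Camera placed the list downwards at adjusted p = 0.0259 (0.602 with an estimated correlation), which did not pass with upper-quartile factors (0.101) or without Gls_cko replicate 1, 2 or 3 (0.323, 0.0631 and 0.171). After trend removal 4 members rose and 1 fell. Lipid genes gave 2 rises and 4 falls among 30 tested, and 2 and 3 when adjusted over the list alone, with camera downwards at adjusted p = 0.378 (0.718 with an estimated correlation) and a median of −1.11 that was 0.30 after trend removal. Dgat1 and Dgat2, which make triglycerides, rose (2.89 and 3.00), Lipa, the lysosomal acid lipase, fell (−1.74), and Cpt2, of fatty acid oxidation, was at least 764-fold lower. Without control replicate 1, none of these lipid genes passed (adjusted p from 0.0556 to 0.0733). Dgat1 and Dgat2 also did not pass without control replicate 2 or 3, Cpt2 without control replicate 3 (0.0507), Dgat1 with library size only (0.0574) or Lipa with voom weights (0.148). Leaving out Gls_cko replicate 1 gave 2.24 for Dgat1, 2.32 for Dgat2 and a bound of 299 for Cpt2.

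Secreted factors also went both ways. Serpinb2 and F10, of fibrinolysis and coagulation, rose (log2 fold changes 4.73 and 3.41), as did Thbs1, encoding thrombospondin 1 (2.29). Of 22 tested complement and coagulation genes, 6 rose and 4 fell, and 7 rose and 5 fell when adjusted over the list alone, with camera upwards at adjusted p = 0.157 (0.514 with an estimated correlation) although the median was −0.84. After trend removal this median was 0.22. Mmp8, the neutrophil collagenase, rose from 17.2 ± 6.51 to 770 ± 184 CPM, Mmp3 was at least 310-fold lower, and Timp3, an inhibitor of these proteases, fell (−10.70). Timp3 had 4 counts in Gls_cko, all in replicate 3, and was at least 2370-fold lower without that library. It stood at −9.93 without Gls_cko replicate 1 and −9.67 without control replicate 2. Among 25 tested matrix remodelling genes, 3 rose and 4 fell, and 4 rose and 4 fell when adjusted over the list alone, with camera downwards at adjusted p = 0.743 (0.852 with an estimated correlation). Inhba, of activin A, rose (2.98) and Bmp2 was at least 978-fold lower. Mmp3 did not pass without control replicate 1, 2 or 3 (adjusted p = 0.0709, 0.0515 and 0.0628). The bounds of Mmp3 and Bmp2 were 121 and 383 without Gls_cko replicate 1. Of 26 tested growth and angiogenic factors, 3 rose and 8 fell, and 4 rose and 10 fell when adjusted over the list alone, with camera downwards at adjusted p = 0.705 (0.751 with an estimated correlation). Without control replicate 1 or 3, 2 of these factors fell.

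Many markers of structural skin cells fell. Cdh5, the cadherin of endothelial junctions, was at least 5559-fold lower, and Egfl7, of endothelial cells, had 8007 counts over the controls and 1 over Gls_cko, a ratio of 6460 (95% interval 1160 to 255000). Control replicate 2 stood apart from the other controls, with 16430 of 20680 counts of Cdh5 and 6415 of 8007 of Egfl7. Without it the bound of Cdh5 was 1950 and the ratio of Egfl7 2190, and without Gls_cko replicate 1 they were 2180 and 2530. Egfl7 was at least 1560-fold lower without Gls_cko replicate 3. Of 20 tested endothelial, pericyte and lymphatic markers, 0 rose and 14 fell in the edgeR test (0 and 16 at an unadjusted p under 0.05), and 15 fell when adjusted over the list alone, with camera downwards at adjusted p = 8.8e-08 (0.443 with an estimated correlation). Their median was −12.70, or −9.91 with genes at 0 counts set to their bound. Col3a1, a fibrillar collagen, fell from 205 ± 63.0 to 13.8 ± 6.03 CPM (−3.89), and Col6a1 was at least 2589-fold lower. Of 27 tested fibroblast markers, 0 rose and 12 fell in the edgeR test (1 and 15 at an unadjusted p under 0.05), and 1 rose and 14 fell when adjusted over the list alone, with camera downwards at adjusted p = 0.000227 (0.443 with an estimated correlation). Krt14, a keratin of basal keratinocytes, was at least 1479-fold lower, whereas Lamb3, of laminin 332, rose (5.45). Among 24 tested keratinocyte markers, 1 rose and 16 fell, and 2 rose and 16 fell when adjusted over the list alone, with camera downwards at adjusted p = 0.00514 (0.524 with an estimated correlation). Their median was −9.45, or −6.36 with genes at 0 counts set to their bound, and with the stricter filter the keratinocyte call was lost (0.147). Krt14 did not pass without control replicate 1 (edgeR adjusted p = 0.0526), nor Col3a1 with voom weights (0.114). The bounds of Col6a1 and Krt14 were 1260 and 744 without control replicate 2, where Lamb3 stood at 6.69, and 1010 and 579 without Gls_cko replicate 1. Without control replicate 1, 7 endothelial, 4 fibroblast and 3 keratinocyte markers fell.

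Some lymphocyte, basophil and red cell transcripts rose. Gzma, a granule protease of cytotoxic lymphocytes, rose from 0.191 ± 0.161 to 144 ± 4.47 CPM, and Cd3d, of the T cell receptor complex, by a log2 fold change of 7.82. Of 18 tested T and NK cell markers, 10 rose and 0 fell in the edgeR test (13 and 0 at an unadjusted p under 0.05), and 13 rose when adjusted over the list alone, with camera adjusted p = 6.6e-10 (0.226 with an estimated correlation). Mcpt8, a basophil protease, rose from 0.0205 ± 0.0188 to 44.3 ± 20.3 CPM, and Hdc, the histidine decarboxylase, from 31.0 ± 9.92 to 2932 ± 1592 CPM. Hdc is a member of the neutrophil list as well, so its rise is not particular to basophils or mast cells. Of 9 tested markers of mast cells, basophils and eosinophils, 3 rose and 0 fell in the edgeR test (5 and 0 at an unadjusted p under 0.05), and 5 rose when adjusted over the list alone, with camera adjusted p = 0.000128 (0.283 with an estimated correlation). Hbb-bs and Hba-a1, haemoglobin chains, rose by log2 fold changes of 10.82 and 11.13, and Alas2, of haem synthesis in red cells, by 8.38. Leaving out control replicate 2 gave log2 fold changes of 10.4 for Gzma, 11.6 for Mcpt8 (10.91 with all libraries) and 11.8 for Hba-a1, which stood at 10.3 without Gls_cko replicate 2, and Alas2 stood at 9.0 without control replicate 3. Of 9 tested erythrocyte and platelet markers, 5 rose and 2 fell, as when adjusted over the list alone, with camera adjusted p = 0.021 (0.514 with an estimated correlation), which did not pass without Gls_cko replicate 2 or 3 (0.0632 and 0.0501). Ccr7, the homing receptor of mature dendritic cells, and Ccl22, a chemokine they make, rose (5.86 and 6.71), Ccl22 with overlapping groups, and Cd207, a Langerhans cell lectin, was at least 28.5-fold lower. Ccl22 did not pass when any library other than Gls_cko replicate 2 was left out (adjusted p 0.0834 to 0.156), with library size only (0.0717), the stricter filter (0.0583), limma-voom (0.176), robust dispersion (0.0537) or after thinning (0.0505). With limma-voom, Ccr7 (0.0921) and Hba-a1 (0.0894) did not pass. The value of Ccl22 was 7.30 without control replicate 2, 7.31 without Gls_cko replicate 2 and 5.93 without Gls_cko replicate 3, where Ccr7 stood at 5.22, and the bound of Cd207 was 11.2 without Gls_cko replicate 1. Of 17 tested dendritic and Langerhans cell markers, 3 rose and 1 fell, and 2 rose and 1 fell when adjusted over the list alone, with camera adjusted p = 0.0201 (0.514 with an estimated correlation), which did not pass without Gls_cko replicate 3 (0.0501), with the stricter filter (0.0995) or after thinning (0.0858).

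Signs of RNA quality and cell handling differed between the genotypes. Mitochondrially encoded genes took 0.774%, 0.987% and 0.647% of counts in the controls and 1.47%, 4.41% and 1.24% in Gls_cko. Exact 95% intervals ran from 0.772% to 0.777%, 0.985% to 0.989% and 0.645% to 0.649% in the controls, and from 1.473% to 1.477%, 4.406% to 4.420% and 1.236% to 1.242% in Gls_cko. Of 15 tested, 4 rose and 0 fell in the edgeR test (11 and 0 at an unadjusted p under 0.05), and 7 rose when adjusted over the list alone, with camera adjusted p = 3.3e-07 (0.443 with an estimated correlation). Their median was 2.39, and −0.55 after trend removal. In edgeR without control replicate 1, 2 or 3, 0 of them passed, and 4, 5 and 3 were higher at an unadjusted p under 0.05. Cytosolic ribosomal protein genes gave 18 rises and 0 falls in the edgeR test (28 and 0 at an unadjusted p under 0.05) among 61 tested, and 23 rises when adjusted over the list alone, with camera adjusted p = 1.1e-19 (0.226 with an estimated correlation) and a median of 0.78. With library size only, 4 of them rose. Fosb, Jun, Junb and Egr1, immediate early genes that tissue digestion can induce, fell (log2 fold changes −3.58, −3.49, −4.72 and −1.77), but stood at 0.16, 0.15, −1.27 and 2.07 after trend removal, where none passed. Of 34 tested dissociation genes, 9 rose and 7 fell, as when adjusted over the list alone, with camera upwards at adjusted p = 0.26 (0.514 with an estimated correlation) and a median of −0.09 that was 0.25 with upper-quartile factors. In edgeR without control replicate 1, 2 or 3, 0 dissociation genes rose, with 9 higher at an unadjusted p under 0.05 in each.

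The 8 largest rises among genes of at least 5 CPM came from few or no counts in the controls. Ceacam10, Ifi44l, Klra7, Apol11b and Camp, the last an antimicrobial peptide of neutrophil granules, had 0 counts in the controls and were at least 2803-fold, 3159-fold, 1813-fold, 1263-fold and 1528-fold higher. Olfm4, of neutrophil granules, had 1 count over the controls and 5141 over Gls_cko, a ratio of 6370 (95% interval 1140 to 252000). Stfa2, of the stefin A family, had 2 and 13569 counts, a ratio of 8410 (95% interval 2330 to 69500). Prss34, a basophil protease, rose by a log2 fold change of 12.08, with 4 control counts, all in replicate 2. Prss34 was at least 3400-fold higher without that library, and its log2 fold change was 11.1 without Gls_cko replicate 3. The 5 bounds were 1640, 1850, 1060, 740 and 896 without control replicate 2, that of Apol11b was 2340 without Gls_cko replicate 1 and 688 without Gls_cko replicate 2, and that of Camp was 2370 without Gls_cko replicate 1. Olfm4 was at least 1240-fold higher without control replicate 2 and had a ratio of 10400 without Gls_cko replicate 1. Stfa2 was at least 4060-fold higher without control replicate 1, with ratios of 4930 without control replicate 2 and 5300 without Gls_cko replicate 1. The 8 largest falls had 0 counts in Gls_cko. Plvap and Tm4sf1, of endothelial cells, were at least 18640-fold and 6020-fold lower, and Rgs5, of pericytes, at least 16060-fold lower. Sparcl1, Adamts4, Fbln5 and Xylt2, of extracellular matrix and its modification, were at least 12110-fold, 8998-fold, 7790-fold and 7463-fold lower. Cd209f was the remaining gene. Control replicate 2 held 57081 of 69355 counts of Plvap, and without it the bounds of Plvap, Tm4sf1, Rgs5, Sparcl1, Adamts4 and Fbln5 were 5630, 2140, 7000, 4620, 2690 and 3360. Without Gls_cko replicate 1, the deepest of its group, they were 7300, 2360, 6290, 4740, 3520 and 3050, and that of Xylt2 was 2920. The edgeR adjusted p values of these 16 genes ranged from 0.00302 to 0.0136. With voom weights 13 of the 16 passed, all but Plvap (0.0713), Sparcl1 (0.0619) and Adamts4 (0.0614).

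Of the 43 lists tested, 25 passed camera, 18 upwards and 7 downwards, whereas 0 passed in camera with an estimated correlation (8 at an unadjusted p under 0.05) and 25 passed in fry. Only 16 lists passed both camera and fry, while 9 passed camera alone and 9 fry alone. Those of camera alone included oxidative phosphorylation (fry adjusted p = 0.14) and interferon genes (0.14), and those of fry alone glutamine metabolism (0.0113). In 20 simulated sets without change, 18 of these 25 lists were called more than 1 time in the same direction. Upward calls came in 20 sets for NF-kB targets and ribosomal proteins, and 19 for oxidative phosphorylation and pro-inflammatory genes. They came in 18 for neutrophil markers, neutrophil-attracting genes, monocyte markers and NRF2 genes, and 16 for interferon genes. MHC class II, hypoxia and erythrocyte lists had 8 each, mitochondrial genes 7 and resolution mediators 5. T and NK cell markers had 4, and mast cell, basophil and eosinophil markers 0. Downward calls came in 6 sets for endothelial, 3 for fibroblast and 2 for keratinocyte markers. A camera call of a list often called in the same direction without change does not show a change. Lysosome genes and macrophage identity markers, called downwards in the real data, had upward calls in 19 and 14 sets. The fold changes also went with GC content: the median ran from 0.33 in the decile of genes with the lowest GC content to −2.53 in the highest, with a Spearman rho of −0.267 across genes, which are not independent replicates. The median of all genes was −0.66, and it shifted by −0.14 with RLE factors, 0.30 with upper-quartile factors, −0.71 with library size only and 0.58 with the trend removed. The number of changed genes was 2032, 3284 and 2552 without control replicate 1, 2 or 3, and 5407, 8063 and 6920 without Gls_cko replicate 1, 2 or 3, and the counts of list members moved with it. Of 144 named genes that passed, 34, 18 and 32 did not pass without control replicate 1, 2 or 3, and 2, 0 and 3 without Gls_cko replicate 1, 2 or 3, all in the same direction.

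**Figure D3:**
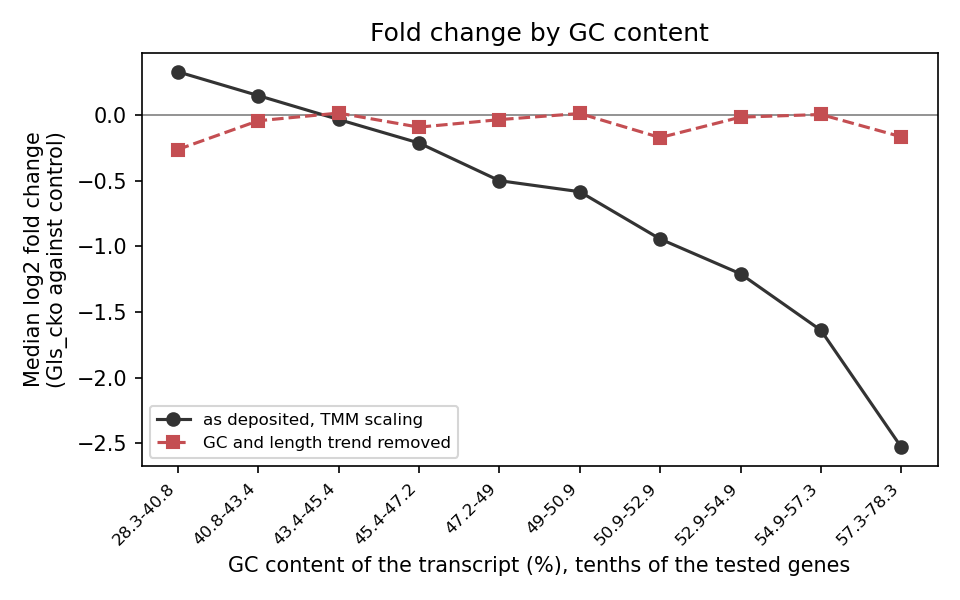
Median log2 fold change (Gls_cko against control) of the tested genes in each decile of GC content, before and after removal of each library's trend with GC content and exon length. Before removal the median ran from 0.33 to −2.53.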

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

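Thinning, voom with library weights, cameraPR and removal of the trend with GC content and length were chosen after the data were seen. With RLE factors all 144 named genes that had passed kept their call and direction, and 142 did with upper-quartile factors, 143 with DESeq2, 141 with limma-voom, 134 with library size only and 117 after trend removal. Gls kept its direction in all alternatives but did not pass with upper-quartile factors (log2 fold change −1.86, adjusted p = 0.0613), without a filter (−2.24, 0.0536), with the stricter filter (−2.06, 0.0574), with the replicate block (−2.40, 0.173) or after trend removal (−2.16, 0.0652), in a range of adjusted p from 0.0049 to 0.173, and stood between −2.87 and −1.75 with a library left out. Library size only gave 674 higher genes. The stricter filter, which tested 12503 genes, gave 2562 changed and 1398 lower genes, and DESeq2, which tested 30150, gave 7616 and 5878. The replicate numbers are not stated to pair the samples. Libraries of the same number correlated at 0.0174, 0.0191 and −0.00362 across genes, which gives no sign of pairing. Given the large spread among the Gls_cko libraries, this cannot exclude pairing or a shared batch. A block on these numbers gave 224 changed genes, 182 higher and 42 lower. With it, 7 of the 16 genes with the largest changes passed, and 55 of the 144 named genes kept their call. With a library left out, 2032 to 8063 genes changed, 450 to 2578 higher and 1582 to 5485 lower. With the correlation estimated per list, 0 of the 25 lists passed camera (8 of 43 at an unadjusted p under 0.05).

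Some directions turned. With library size only, Uty stood at −0.13, and Kdm5d between −0.988 and 0.0752 with a library left out. After trend removal the log2 fold change was 0.45 for Slc1a5, 1.03 for Glul, 0.46 for Gls2, 0.96 for Ogdh, 0.89 for Acly, −0.20 for Cox7b, 1.62 for Ehmt2, 0.81 for Hdac5, 2.10 for Tap2, 2.95 for Tapbp, −0.86 for B2m, 0.20 for Grn, 0.0672 for Csf1r, 0.16 for Fosb, 0.15 for Jun and 2.07 for Egr1, none of them past the threshold. In fry, direction differed from camera for the TCA cycle (adjusted p = 0.14), ATF4 targets (0.793), histone methyltransferases, acetyltransferases and deacetylases (0.00764), MHC class I (0.314), B cells (0.678), muscle and adipocytes (0.147) and dissociation genes (0.00967). In camera, direction turned for repair genes with upper-quartile factors (0.86) and with the block (0.632), for muscle and adipocyte markers with the block (0.925) and thinned (0.968), and for MHC class I thinned (0.968) and in cameraPR (0.974). With a library left out it also turned for muscle and adipocyte markers (0.656 to 0.923), monocyte and lymphocyte chemokines (0.459 to 0.988), repair genes (0.376 to 0.947), matrix remodelling (0.5 to 0.988) and B cell markers (0.49 to 0.988). Apart from what the fewer genes or libraries account for, the cause was not tested. A fall that was lost or turned after trend removal is not thereby shown to come from GC content or length. Tapbp turned from −0.996 to 2.95, although it lay at 199 to 224 CPM in the Gls_cko libraries and 412 to 428 CPM in the controls. Depth limits what can be said of genes at 0 counts, since 3 counts correspond to 0.0233 to 0.121 CPM. Some genes also had 0 counts in a Gls_cko library while another Gls_cko library held at least 50 CPM. There were 8, 44 and 3 such genes in Gls_cko replicates 1, 2 and 3, and 0 in each control. Bounds at 0 counts therefore cover counting only, and do not bound the level in the cells.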

Other observations

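Hypoxia, cholesterol and antioxidant genes gave a mixed picture of rises and falls. Ero1l, an endoplasmic reticulum oxidase, and Bnip3 and Higd1a, mitochondrial proteins induced by hypoxia, rose (log2 fold changes 2.55, 1.97 and 2.58), whereas Car9, a carbonic anhydrase, was at least 189-fold lower. Bnip3 did not pass after removal of the trend with GC content and length (1.22), nor Car9 without control replicate 1, 2 or 3 (edgeR adjusted p = 0.0704, 0.0502 and 0.0604, in a range over its alternatives from 1.26e-10 to 0.173), and its bound was 74.1 without Gls_cko replicate 1. Of 25 tested hypoxia genes, 6 rose and 3 fell, and 8 rose and 3 fell when adjusted over the list alone, with camera upwards at adjusted p = 0.00536 (0.226 with an estimated correlation). Their median was 0.51, but −0.34 with library size only, and their mean was −0.58. Msmo1 and Sc5d, of cholesterol synthesis, rose (1.51 and 2.92) and Dhcr24, of its last steps, was at least 118-fold lower, though none of these passed without control replicate 1 or 3, nor Msmo1 with library size only (0.131), and the bound of Dhcr24 was 46.2 without Gls_cko replicate 1. Of 21 tested cholesterol genes, 3 rose and 1 fell, as when adjusted over the list alone, with camera upwards at adjusted p = 0.0204 (0.443 with an estimated correlation), a call lost with the stricter filter (0.0698). Gsr, the glutathione reductase, rose from 47.0 ± 15.8 to 920 ± 257 CPM, and Nfe2l2, encoding NRF2, and Txn1, encoding thioredoxin, rose (2.79 and 1.65), Txn1 not after trend removal (0.21), with library size only (0.91) or without control replicate 3 (adjusted p = 0.0558). In the NRF2 list, 7 of 25 tested rose and 2 fell, as when adjusted over the list alone, with camera upwards at adjusted p = 0.000975 (0.478 with an estimated correlation). Its median was −0.14, but 0.17 with upper-quartile factors, and its mean was 0.09.

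Proliferation genes and markers of rarer cells were lower or gave few calls. Ccne1, a cyclin of S phase entry, and Plk1, a mitotic kinase, were at least 447-fold and 438-fold lower, and neither passed without control replicate 1 or 3, nor Plk1 without control replicate 2 (edgeR adjusted p = 0.0502). Their bounds were 175 and 171 without Gls_cko replicate 1, and 263 for Plk1 without control replicate 2. Of 43 tested cell cycle genes, 0 rose and 2 fell in the edgeR test (1 and 2 at an unadjusted p under 0.05), as when adjusted over the list alone, with camera downwards at adjusted p = 0.134 (0.752 with an estimated correlation), which passed without control replicate 1 (0.0449) and without Gls_cko replicate 3 (0.0281). Igkc, the immunoglobulin kappa constant region, rose (log2 fold change 6.88), and Ighd, the constant region of IgD, was at least 20.2-fold lower. Among 6 tested B and plasma cell markers, 1 rose and 1 fell, as when adjusted over the list alone, with camera upwards at adjusted p = 0.658 (0.752 with an estimated correlation) and a median of 0.51 that was −0.12 with library size only. Retn, encoding resistin, rose (7.91), and Ckm and Actn3, of skeletal muscle, were at least 53.5-fold and 68.3-fold lower. Igkc, Ckm and Actn3 did not pass without control replicate 1, nor Igkc, Actn3 and Retn without control replicate 3. Igkc stood at 8.14 without control replicate 2 and 5.90 without Gls_cko replicate 2, and Retn at 8.86 without control replicate 1 and 7.03 without Gls_cko replicate 1. The bounds of Ighd, Ckm and Actn3 were 7.90, 20.9 and 26.7 without Gls_cko replicate 1, and those of Ckm and Actn3 were 32.1 and 29.4 without control replicate 2. Of 9 tested muscle and adipocyte markers, 1 rose and 3 fell, and 2 rose and 3 fell when adjusted over the list alone, with camera upwards at adjusted p = 0.796 (0.852 with an estimated correlation). Their median was 0.15, but −0.70 with library size only, and their mean was −1.57. Ngfr, Cdh19 and Plp1, of Schwann cells, were at least 590-fold, 85.5-fold and 577-fold lower, and none passed without control replicate 1, 2 or 3. Their bounds were 231, 33.5 and 226 without Gls_cko replicate 1, and 225 for Plp1 without control replicate 2. Of 9 tested Schwann cell and melanocyte markers, 0 rose and 6 fell in the edgeR test (0 and 6 at an unadjusted p under 0.05), as when adjusted over the list alone. Camera placed them downwards at adjusted p = 0.0373 (0.496 with an estimated correlation), which did not pass without control replicate 2 or Gls_cko replicate 1 or 3 (0.0598, 0.0607 and 0.148). Their median was −8.06, or −5.08 with genes at 0 counts set to their bound. Among 4 tested sex-linked genes of the mice, too few for camera, 2 rose and 0 fell in the edgeR test (2 and 0 at an unadjusted p under 0.05), as when adjusted over the list alone. Eif2s3y and Ddx3y, of the Y chromosome, rose (2.51 and 3.13, Ddx3y 2.49 without Gls_cko replicate 2), while Uty (0.68) and Kdm5d (−0.55) did not pass.

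All tests of the hypotheses that follow were chosen after the results they explain were seen. Neutrophil markers were higher and macrophage markers lower in Gls_cko, by medians of 7.36 and −2.12. A lower share of macrophages alone would raise markers of other cell types alike, but fibroblast markers had a median of −3.73 (upper quartile −2.82) while the lower quartile of neutrophil markers was 4.64. GC content and length as the whole cause are argued against by the median of the neutrophil markers after trend removal, 7.53. This covers the neutrophil markers only. Most of the fall in the median of the macrophage markers went with the trend, as given above, so GC content and length stay open for them. Neutrophil RNA in the bead-isolated fraction stays open. That 79.3% of the tested markers (23 of 29) lay above every control in every Gls_cko library restates the pattern and decides nothing. Ngp, Ltf and Mpo, abundant in immature neutrophils and named after their values were seen, were not among the 23. Camp, a granule gene of the same list, was among them, so these single genes decide nothing either. Transcripts of other cell types rose alongside, Hbb-bs from 1.23 to 2226 CPM, Gzma from 0.191 to 144, Mcpt8 from 0.0205 to 44.3 and Cd3d by 7.82 on the log2 scale, as carry-over of blood cells would bring, though they do not show it for neutrophils. Neutrophil RNA cannot be told apart from expression by the knockout macrophages. Of the 29 markers, 7 stand in another list and 19 reached 1 CPM in the controls, and no purity value was analysed here. The F4/80 beads should leave neutrophils behind, but also red cells, T cells and basophils, whose transcripts rose. The use of beads therefore does not argue against neutrophil RNA.

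Gls_cko libraries held fewer genes and spread more than the controls. Sequencing depth as the cause is argued against by the 12478 genes at most in a Gls_cko library after thinning, against at least 15926 in a control. GC content as the whole cause is argued against by the genes in the lowest quintile of GC content, of which at most 73.6% were detected in a Gls_cko library and at least 93.4% in each control. Few starting RNA molecules may account for it, since 8, 44 and 3 genes had 0 counts in Gls_cko replicates 1, 2 and 3 while another Gls_cko library held at least 50 CPM, against 0 in each control. That lowest number, 3, cannot be told apart from real differences between the pooled wounds, as no RNA amount was analysed here, and the knockout itself stays open and untested.

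Lyz2 was near 0 in the Gls_cko libraries, at 1.67 ± 1.88 CPM against 8655 ± 2203. Fewer macrophages as the whole cause are argued against by the other macrophage identity markers, none of which stood below −5.19 (SE 0.62, C1qc) while Lyz2 fell by 12.31 (SE 1.26) on the log2 scale. Lyz1, its near-identical copy, rose from 54.3 to 332 CPM (edgeR adjusted p = 0.0154), so reads of Lyz1 make up nearly all of the sum of both in Gls_cko, 334 CPM against 8709 in the controls (log2 ratio −4.70). A variant that sends reads of Lyz2 to Lyz1, together with fewer macrophages, was not tested. Loss of transcripts in libraries of low complexity, striking abundant genes alike, is argued against by the 79 genes with at least 1000 CPM in the controls. Only 2 of them, Lyz2 and Lars2 (named after its values were seen), fell more than 100-fold in every Gls_cko library. A loss particular to few genes cannot be told apart on these counts, because Lars2 fell as well. Disruption of the Lyz2 gene itself, as by a Cre insertion on both alleles, also stays open. The 8 tested genes within 500 kb had a median log2 fold change of 0.77, which decides nothing, since neighbours that do not fall with Lyz2 are expected under the other explanations as well. The labels used here name no Cre line.

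The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05, and the real split was 1 of the 10 with as large a result for genes and for lists. It gave 4452 changed genes in edgeR, and the highest of the other splits 0 (110 at an unadjusted p under 0.05). For gene lists in camera the real split gave 25 and the highest of the other splits 21.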
